A study of Mus musculus with 31 samples.

How the data were processed

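Mouse oocytes (B6D2F1) were profiled by reduced representation bisulfite sequencing, which cuts DNA with the enzyme MspI at CCGG and so samples mostly CpG-rich sequence. The 31 libraries fall into 9 stages that the titles number from Type1 to Type7, with 3 to 5 libraries each, and into 4 follicle classes: primordial (Type1, Type2), primary (Type3a, Type3b), secondary (Type4, Type5a, Type5b) and antral (Type6, Type7). Another label naming embryo stages contradicts the titles and was not used. Per the labels' protocols, lysed oocytes were digested, ligated to premethylated adaptors, bisulfite converted, amplified by PCR and size-selected at 200 to 700 bp. Per the submitters' processing notes, BSMAP 2.89 and the mouse build mm9 were used; the methylation caller and any trimming are not given in the sources used here. Nothing in the labels says whether libraries of a stage came from separate animals, or how many oocytes each held, so p-values measure only the spread between these libraries, which may be technical.

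The deposited files give, per CpG site, the count of all reads and of methylated reads. The deposited files also give the methylated fraction per site and the reads of each strand. From the values, no site with fewer than 3 reads is listed. The reads carry no molecular identifiers, so PCR copies count as separate reads and intervals cover counting error only. Bisulfite reads turn unmethylated C into T, so a strain variant from C to T reads as unmethylated, and incomplete conversion reads as methylated. Cytosines filled in at MspI ends also read as unmethylated unless trimmed.

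Reads over sites ran from 7949652 to 60361665 per library, and sites with at least 5 reads from 296800 to 775364. The median was 9 to 28 reads per site, and the 1% of sites with most reads took 15.3 to 40.2% of the reads. Among 41 pairs of libraries of a stage, at most 1.01% of sites with at least 20 reads in both had identical counts, so no library was treated as a duplicate.

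Sites with at least 5 reads were summed into fixed 100-bp tiles holding at least 3 such sites. Of 163350 tiles measured in any library, 39619 common tiles were measured in at least 2 libraries of every stage (37657 autosomal, 1955 on X, 7 on Y). The mean level of a library is the mean over the common tiles it measured. These ran from 27519 (Type5a replicate 6) to 39469 (Type1 replicate 3), and 8915 tiles were measured in all 31 libraries. Mean levels thus cover different tiles, and the effect of this was not tested. Tiles were tested with a quasi-binomial model of methylated and total reads with stage as factor over all libraries. The dispersion was moderated over tiles as in limma's squeezeVar and floored at 1, contrasts were tested by F test, and p-values were adjusted by Benjamini-Hochberg within a contrast. A tile was called at an adjusted p under 0.05 and a difference of at least 20 percentage points. Library values were compared by two-sided exact permutation tests, or by 100000 resamples where a group held 10 or more.

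On simulated reads for 39619 tiles, Type5b against Type5a, the model called 18, 60, 62 and 74% of 50 tiles each changed by 20, 30, 40 and 50 points, and 0.0507% of unchanged tiles; 7.20% of unchanged tiles had an unadjusted p under 0.05. For Type7 against Type1 the shares were 26, 62, 52 and 64%, with 0.0939% of unchanged tiles called and 8.60% at an unadjusted p under 0.05. Changes were thus often missed at these group sizes.

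CpG density is the number of sites listed in any library within 1 kb around a tile. It counts only sites the assay reached, not every CpG of the sequence, so a tile on an isolated fragment counts as CpG-poor. The X measure of a library is the mean level of its CpG-dense X tiles (at least 60 sites per kb, 63 tiles) minus that of its 2902 CpG-dense autosomal tiles. Named tiles are the 5 per direction with the largest difference among called tiles without overlap of the libraries compared, in genome order where tied; chance leaves 33.3% of tiles without overlap at 2 libraries against 2 (15 of the named tiles), 20% at 2 against 3 (26), 10% at 3 against 3 (5) and 3.57% at 3 against 5 (2). The gene annotation given is of another build than mm9, so genes were not placed, and the planned promoter and gene-list tests were not run.

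The tests, thresholds and most alternatives (other read minimums, tile sizes and site minimums, at most 10 reads per site, limma, edgeR, a fit on 2 stages, a replicate block, each library left out) were set before the data were examined. Leaving out the 9 libraries with an X measure above 0, and limma with the X measure as covariate, were added after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and edgeR 4.0.16 were used.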

Results

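DNA methylation was measured at 1419929 CpG sites in 31 libraries of mouse oocytes from 9 stages of follicle growth, from primordial to antral follicles. Type4 and Type5a had 5 libraries and the other 7 stages 3. Mouse oocytes lose most DNA methylation as early germ cells and regain it after birth while they grow, so the series asks when and where methylation returns. Tile coordinates are mm9, 1-based, and levels are percentages of methylated reads with the SD between libraries.

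Methylation was low in oocytes of primordial follicles and highest in those of antral follicles. The mean tile level was 17.6% ± 4.24 (SD, n = 3) in Type1 and 16% ± 0.955 in Type2. It was 18.9% ± 7.44 in Type3a and 21.9% ± 2.20 in Type3b. In secondary follicles it was 25.9% ± 6.37 (n = 5) in Type4, 23.2% ± 3.61 (n = 5) in Type5a and 28.5% ± 1.66 (n = 3) in Type5b. In antral follicles it was 36.5% ± 1.87 in Type6 and 33.8% ± 0.414 in Type7. Stages held 76.2% of the variance between libraries (permutation p = 5e-05). By class, antral oocytes lay 9.67 points above secondary ones (permutation p = 0.00038, adjusted 0.00114). Secondary oocytes lay 5.12 points above primary ones (permutation p = 0.0491, adjusted 0.0736), which did not pass the correction, nor did the 3.58 points between primary and primordial (exact permutation p = 0.171, adjusted 0.171). Type6 minus Type5b was 7.99 points and Type5b minus Type5a 5.28, an order that turned to 6.48 and 7.65 without the 9 libraries of X measure above 0 (CpG-dense X minus autosomal level). That left 1 library in Type6 and 3 in Type5a. No difference between adjacent stages passed (lowest adjusted p 0.267), and 3 against 3 libraries cannot give an exact p below 0.1.

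**Figure D1:**
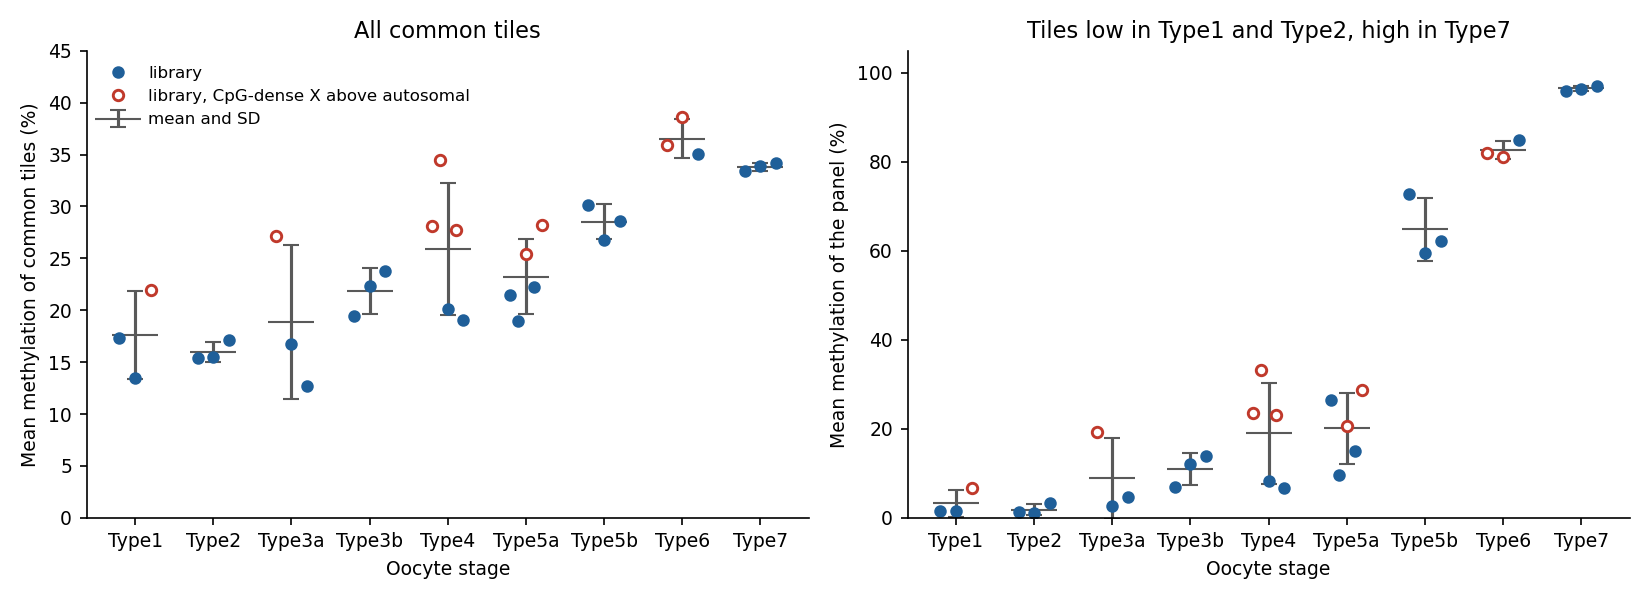
Mean methylation level (%, left) and level of the 2553 tiles below 10% in Type1 and Type2 and above 80% in Type7 (%, right) per library, by stage; lines are the mean and SD, open circles the 9 libraries whose CpG-dense X tiles lie above their autosomal ones. The 2553 tiles went from 20.1% in Type5a to 64.9% in Type5b.

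In tiles low in Type1 and Type2 and high in Type7, the largest difference between adjacent stages lay within secondary follicles, between Type5a and Type5b. The 2553 tiles that were below 10% in Type1 and Type2 and above 80% in Type7 had a level of 3.25% ± 2.98 in Type1, 1.87% in Type2, 8.87% ± 9.03 in Type3a and 11% ± 3.64 in Type3b. They had 19% ± 11.3 in Type4 and 20.1% ± 7.98 in Type5a, and then 64.9% ± 7.04 in Type5b, 82.7% ± 1.99 in Type6 and 96.6% ± 0.595 in Type7. The 44.7 points between Type5a and Type5b had the smallest exact permutation p this design allows (0.0357, adjusted 0.267). The tiles were chosen on Type1, Type2 and Type7, so only the stages between carry information. The X measure, given here because it varied within stages, was 6.75, 10.6 and 9.94 points in Type4 replicates 1, 2 and 5, and their levels of these tiles were 23.6, 33.3 and 23.2%, against 8.18 and 6.65% in replicates 4 and 6.

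Between successive stages up to Type5a, few tiles were called. Type2 was lower than Type1 in 4 of 69548 tiles, among them chromosome 3, 149748901 to 149749000 (95.4% ± 5.24, n = 2, to 43.5% ± 13.3, n = 3). The others were on chromosome 2 at 151169001 (93.1 to 42.3%) and 63562601 (95.4 to 54.3%), and on chromosome 1 at 44665501 (81.7 to 36.9%). Type3a was higher than Type2 in 1 of 59607 tiles (chromosome 19, 18432301 to 18432400, 19.8% ± 10.2 to 64.2% ± 21.4). Type4 was higher than Type3b in 2 tiles and lower in 2 of 63468, with a tile on X at 27455401 higher (16.1% ± 4.17 to 65.6% ± 24.4). The other, on chromosome 7 at 23613801 (35.8% ± 24.8 to 67% ± 29.5), had overlapping libraries and was picked after its values were seen. One on chromosome 8 at 3452101 was lower (70.6% ± 7.50 to 0%, n = 2 each), as was one on chromosome 16 at 95731101 (58.8% ± 45.8, n = 3, to 1.51% ± 2.13, n = 2). Type3b against Type3a gave 0 calls in 51559 tiles with the quasi-binomial model (1956, or 3.79%, at an unadjusted p under 0.05, 6 with limma, 2 with edgeR). Type5a against Type4 gave 0 calls in 84424 tiles (6083, or 7.21%, at an unadjusted p under 0.05, 100 with limma, 96 with edgeR). On simulated reads, 7.20 and 8.60% of unchanged tiles had such a p, but for Type5b against Type5a and Type7 against Type1. The 2 pairs here, with other group sizes or spread, were not simulated, so these values cannot decide whether the 7.21% is an excess. Without the 9 libraries of X measure above 0 the counts were 20, 1, 73, 61 and 256 in the order of the stages, and among them were 0 of the 4 Type2 tiles, 0 of the 1 Type3a tile and 1 of the 4 Type4 tiles. With at most 10 reads per site the counts were 0 for Type2 and for Type3a, and a fit on the 2 stages gave 0 for Type2 against Type1 and for Type4 against Type3b. Single libraries moved them: Type2 against Type1 had 0 calls without Type1 replicate 1 and 8 without Type2 replicate 1, Type3a against Type2 had 0 without Type2 replicate 3 or Type3a replicate 1 and 2 without Type2 replicate 2, Type4 against Type3b had 12 and 13 without Type4 replicate 4 or 6, and Type5a against Type4 had 6, 18 and 5 without Type4 replicate 1, 2 or 5 and 4, 3, 6 and 19 without Type5a replicate 1, 4, 5 or 7.

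Between Type5a and Type5b, regions gained methylation far more often than they lost it. Of 65397 tiles, 2776 rose and 80 fell. Levels of called tiles, here and in the comparisons below, come from the libraries that chose them, so selection widens the differences. The risen tiles went from 21.8% ± 8.23 (n = 5) to 80.2% ± 6.68 (n = 3) and reached 93.8% ± 0.565 in Type7. The fallen ones went from 48.7% ± 11.4 to 11.9% ± 1.82, but were at 39.7% ± 4.72 in Type6 and 26.9% ± 2.04 in Type7. In Type4 they were at 37.6% ± 10.9. Gains from 0 to 100% were on chromosome 4 at 151751901 (adjusted p 0.00397), 5 at 106161201 (0.00156), 10 at 80069301 (0.00946), and 11 at 70370801 (0.0330) and 101031701 (0.00344). The tile on chromosome 5 was at 58.3% in Type6 and 21.5% in Type7. Losses were on chromosome 16 at 39091001 (92.6% ± 6.18 to 12.5% ± 17.7, n = 2 each), 6 at 112017701 (80.6 to 2.74%), 2 at 174282601 (71.3 to 0%), 8 at 122564001 (69.5 to 0.273%) and 13 at 58757301 (64.1 to 0%). In Type6 these tiles were at 77.6, 49.2, 1.10, 0 and 12.7%, in the same order. Of 2216 risen tiles also tested between Type1 and Type7, 2063 rose there too, against 376 from independent lists. Both lists favour tiles that start low and share the model's dispersion, so part of that excess could arise without a link. The 2856 calls became 676 without Type5b replicate 1, 1725 in a fit on the 2 stages and 1656 with edgeR. With the replicate number as a block they became 55, where the 2 stages share 1 number.

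Between Type5b and Type6, 1103 of 61151 tiles rose and 47 fell. The risen tiles went from 26.2% ± 1.51 to 74.8% ± 2.76 (n = 3 each) and were at 67.6% ± 0.514 in Type7. The fallen ones went from 67.2% ± 7.14 to 22.7% ± 4.04 and were at 57.5% ± 9.90 in Type7. The largest gains were on chromosome 5 at 36113701 (0 to 100%, adjusted p 0.00529) and chromosome 17 at 3350101 (0 to 100%), 3350201 (0 to 99.5%) and 47809601 (0.447 to 98.9%, adjusted p 1.15e-05). Another was on chromosome 13 at 56908501 (0 to 97.8%). The largest losses were on chromosome 17 at 66781801 (90.6% ± 13.3 to 0.314% ± 0.445), chromosome 9 at 43038201 (90.3 to 3.87%), 121186901 (83.1 to 6.35%) and 121186801 (81.7 to 7.58%), and chromosome 11 at 106520901 (97.9 to 19.5%). Of 955 risen tiles tested in both, 557 also rose from Type1 to Type7, against 161 from independent lists, which these lists are not either. The X measure was 1.04 and 1.31 in Type6 replicates 1 and 2 and -4.02 in replicate 3. The 1150 calls became 596, 569 and 658 without Type5b replicate 1, 2 or 3, 693 without Type6 replicate 1, 558 with at most 10 reads per site and 198 in a fit on the 2 stages.

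From Type6 to Type7 changes went both ways, while the mean level was 2.70 points higher in Type6 (exact permutation p = 0.1, the smallest possible, adjusted 0.267). Type7 minus Type6 was -0.353 points over every site a library measures (exact permutation, adjusted p 0.8) and -0.719 with reads pooled over sites (exact permutation, adjusted p 1). Of 61037 tiles, 270 rose, from 24.1% ± 3.47 to 78.6% ± 2.20 (n = 3 each), and 97 fell, from 70.9% ± 5.17 to 27.3% ± 2.26. Selection enlarged the fall: in the autosomal tiles among them Type6 lay 43.6 points above Type7. In autosomal tiles called lower without a library of each stage, the pair left out differed by 11.5 points ± 3.05 (SE, mean of 9 pairs). The fallen tiles were at 38.2% ± 4.03 in Type5b. Gains were on chromosome 2 at 117075601 and 6 at 52241401 (0 to 100%), chromosome 10 at 6079801 (0 to 100%) and 6079901 (0 to 97.8%), and chromosome 9 at 108018001 (2.91 to 100%). The tile on chromosome 6 was at 88.9% in Type5b and those on chromosome 10 at 66.7 and 67.4%. Losses were on chromosome 15 at 26177901 (97.8% ± 0.755 to 1.56% ± 0.505, adjusted p 0.000673), chromosome 14 at 113804201 (100 to 21.5%) and 43316401 (92.1 to 19.5%), X at 36497801 (82.0 to 3.79%) and 13 at 99343901 (77.6 to 0%). The 367 calls became 17 in a fit on the 2 stages, 121 and 235 without Type7 replicate 1 or 2, 572 without Type6 replicate 3 and 648 with limma.

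Over the whole series, 10083 of 58522 tiles were higher in Type7 than in Type1 and 81 lower. The gained tiles went from 15.2% ± 4.80 to 87.6% ± 0.689 (n = 3 each), through 29.5% ± 6.64 in Type5a, 61.6% ± 4.76 in Type5b and 78.6% ± 0.759 in Type6. Gains from 0 to 100%, the first in genome order, were on chromosome 1 at 25267501, 34213601, 36613701, 36614601 and 37468301. Losses were on chromosome 17 at 39983001 (89.0% ± 8.07 to 1.79% ± 2.40, adjusted p 0.00209) and 39983101 (83.3 to 4.77%), 1 at 116031301 (86.8 to 13.2%), 6 at 78888701 (83.6 to 13.7%) and 2 at 111422201 (68.5 to 0%). Gain was rarer where listed CpG sites were dense, a count that also depends on which fragments were captured. Of tiles with 0 to 9 listed sites per kb 32.1% were gained, 23.0% with 10 to 19, 12.0% with 20 to 39, 7.72% with 40 to 59 and 3.80% with 60 or more. The share ran from 13.4% on chromosome 14 to 23.4% on chromosome 5, and was 17.3% on X. The 10164 calls became 5240 and 6422 without Type1 replicate 1 or 3, and 5378 and 6236 without Type7 replicate 1 or 2.

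Gained regions lay together. A tile within 200 bp after a gained tile was itself gained in 71.2% of cases, against 4.31% after a tile not gained, and at 20 to 100 kb the shares were 33.2 and 18.6%. There were 156 runs of at least 5 gained tiles, holding 1071 tiles. The run with most tiles, 112, lay on chromosome 8 from 126062001 to 126147900. Its 41 tiles measured in every stage had 5.67% ± 5.26 in Type1, 16.4% ± 7.82 in Type5a, 68.8% ± 3.52 in Type5b, 81.5% ± 4.36 in Type6 and 95% ± 1.89 in Type7. Tiles recurred there at regular distances, with 51 pairs 1700 bp apart, so they may be copies of a repeat and not independent.

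**Figure D2:**
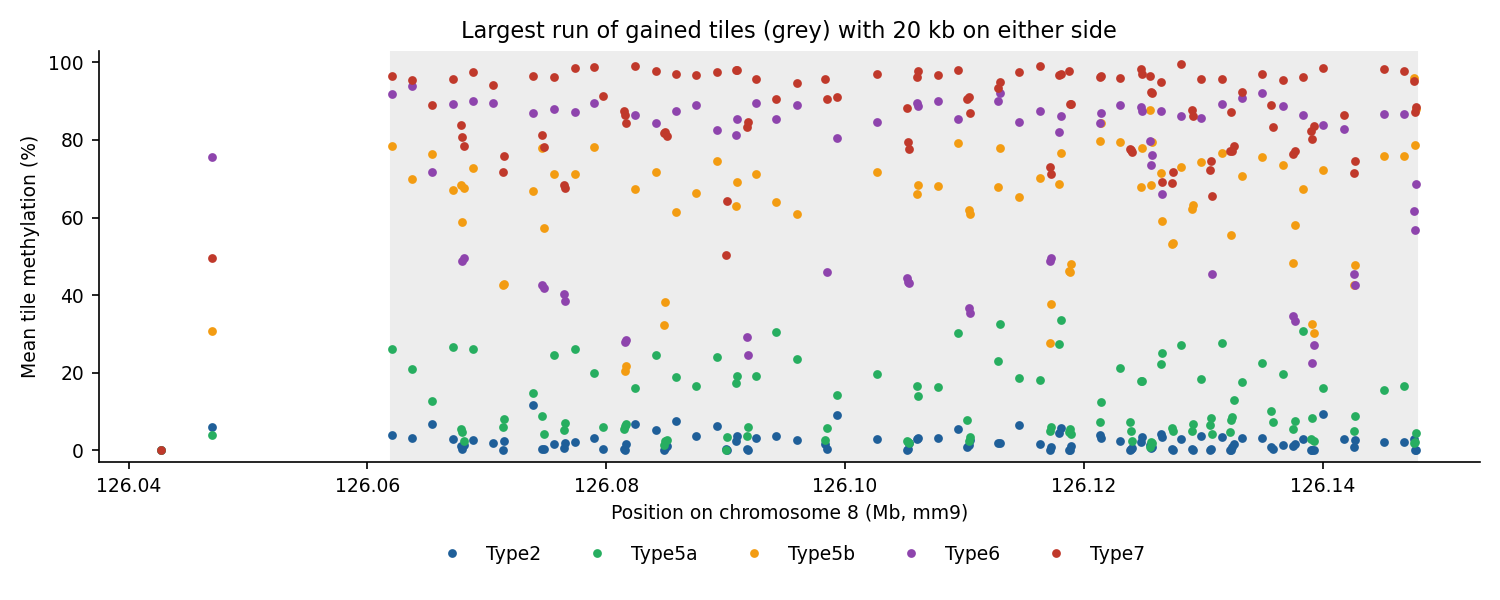
Mean level per tile (%) against position on chromosome 8 (Mb, mm9) in 5 stages, one point per tile measured in at least 2 libraries of the stage; grey marks the run of 112 gained tiles from 126062001 to 126147900. Type2 and Type5a lie low, and Type5b, Type6 and Type7 higher.

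In secondary follicles, gained tiles with dense CpG sites had reached less of their gain than CpG-poor ones. Gained tiles were put in 3 groups by density, and progress was taken as the percentage of the Type1 to Type7 gain reached. In Type5b the CpG-poorest group had reached 68.0% ± 5.17 and the CpG-densest 54.3% ± 9.34 (n = 3). In Type6 the densest group minus the poorest was -9.53 points ± 0.436, below 0 in 3 of 3 libraries. Over the 13 secondary libraries the densest group minus the poorest was -5.11 points ± 5.89, below 0 in 11 (exact sign-flip permutation p = 0.00439). By stage it was -1.20 ± 3.03 in Type4 (below 0 in 3 of 5 libraries), -3.88 ± 3.12 in Type5a (5 of 5) and -13.7 ± 4.36 in Type5b (3 of 3), while it was 1.56 ± 1.56 in Type3a (above 0 in 3 of 3) and 0.986 ± 1.68 in Type3b (2 of 3). The last pair turned to -2.41 ± 3.89 (below 0 in 2 of 3) and -4.09 ± 2.20 (3 of 3) in tiles matched on Type1 and Type7 level. Without the libraries of X measure above 0 it was -6.00 (exact permutation p = 0.0781), no longer past the threshold.

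**Figure D3:**
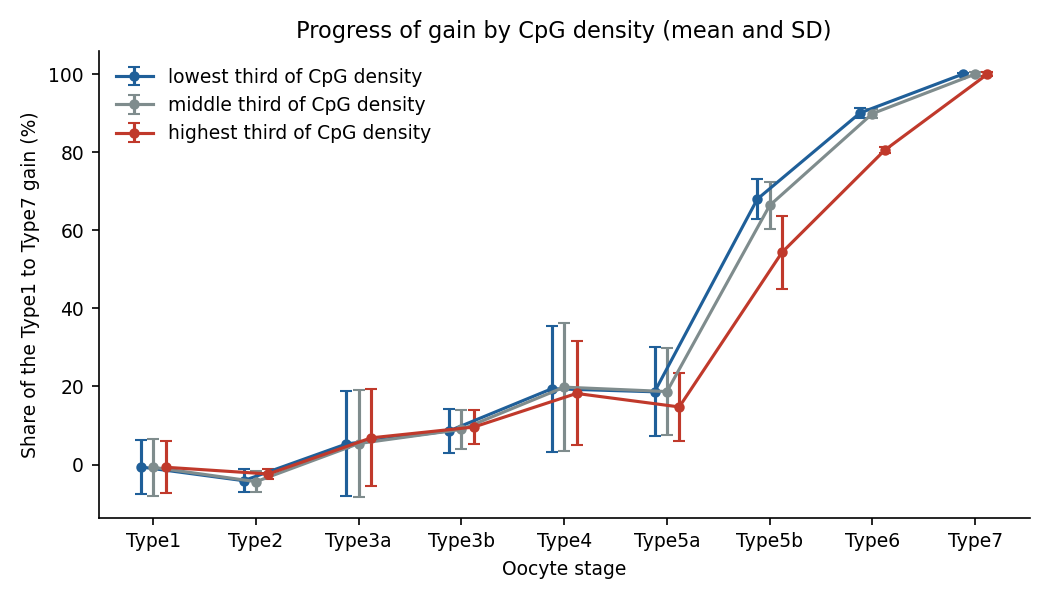
Share of the Type1 to Type7 gain reached (%) by stage for gained tiles in 3 groups of CpG density; points are means over libraries and bars SD. In Type5b the densest group is at 54.3% and the poorest at 68.0%.

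Some regions were already methylated in primordial follicles. In all 3 Type1 libraries, 2475 of 37015 tiles (6.69%) had a level of at least 50%, and 139 at least 80%. The 2475 tiles had a mean of 68.6% ± 2.34 in Type1, 62.6% ± 0.976 in Type2, 74.1% ± 1.33 in Type5b, 83.1% ± 1.4 in Type6 and 78.6% ± 0.528 in Type7; the count became 7051 without Type1 replicate 2.

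Tile levels differed most between paired libraries of one stage in Type4 and Type5a, while the SD of the mean level was largest in Type3a (7.44). At 10 reads per site, the mean difference between tile levels of paired libraries was 13.4 points ± 1.12 (n = 5) in Type4 and 12.2 ± 0.828 (n = 5) in Type5a, against 10.7 ± 0.234 (n = 3) in Type5b, 10.4 ± 0.218 in Type6 and, at the lowest, 6.31 ± 0.232 in Type2. Stages held 89.1% of its variance (permutation p = 1e-05, the smallest possible; values of a stage share pairs, so it is too small). CpG-dense X tiles lay above CpG-dense autosomal tiles in 9 libraries: Type1 replicate 3, Type3a replicate 1, Type4 replicates 1, 2 and 5, Type5a replicates 5 and 7, and Type6 replicates 1 and 2.

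**Figure D4:**
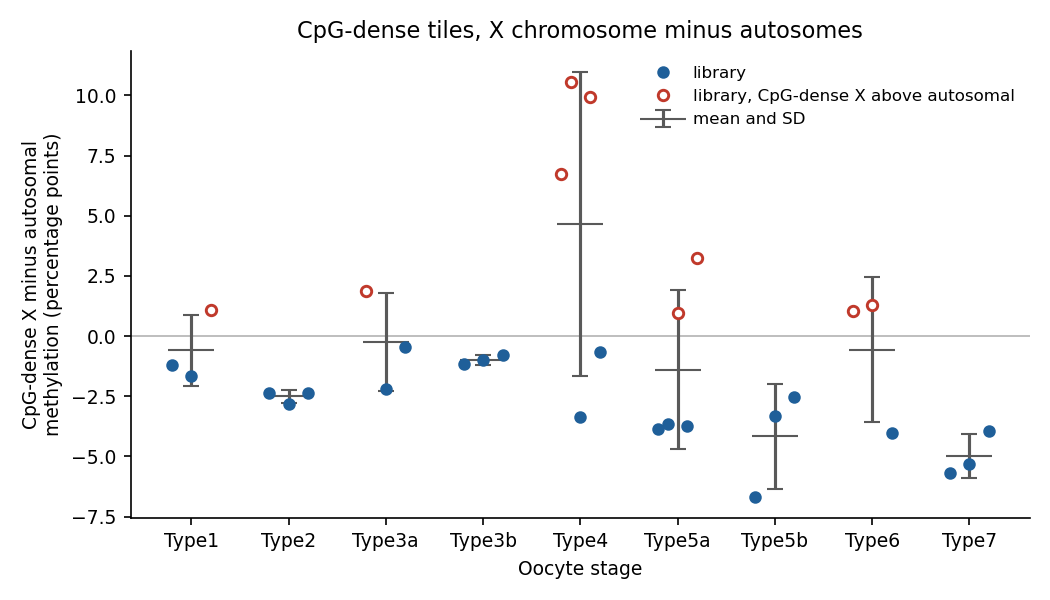
Level of CpG-dense X tiles minus CpG-dense autosomal tiles (percentage points) per library, by stage, with mean and SD. The 3 highest libraries, at 10.6, 9.94 and 6.75, are of Type4.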

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

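The mitochondrial methylation level was planned as a check of unconverted cytosines; the tests of mitochondrial read counts and of explanations in this part were chosen after the results were seen. Mitochondrial sites held 71.6 RPM (reads scaled to the total over sites) on average in secondary and 81.9 RPM in antral libraries, a signal outside the tiles, against 0.596 in primordial and 1.69 in primary ones (secondary against primary, permutation p = 6e-05, adjusted 0.00018). Type5a replicate 6 stood apart from its stage at 493 RPM, and without it the secondary mean was 36.4 RPM (permutation p = 4e-05 against primary); of 20 groups and measures tested 1 stood out this way, and chance gives about 1 in 20. The mitochondrial methylation level ran from 0 to 39%, the highest in Type5a replicate 7, among 20 libraries with at least 100 reads over up to 26 sites, so it gives no common bound on unconverted cytosines. No explanation of these mitochondrial values was tested.

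Libraries of Type4 and of Type5a differed in mean level. With at most 10 reads per site the SD between Type4 libraries was 1.00 times that with all reads. Drawing reads at random leaves the expected level of a site unchanged, so this cannot decide on depth. Mean level and log10 reads showed no clear relation over 10 libraries (Pearson r = 0.0779, permutation p = 0.830, adjusted over 8 relations 0.845). A mix of earlier and later oocytes as the only cause in Type4 is argued against by 3 libraries whose X measure lay above the highest library of any other stage. A mix beside another cause stays open, and in Type5a a mix was not tested. There, replicates 1 and 4 had 26.6 and 9.56% in the tiles low in Type1 and Type2 and high in Type7, at X measures of -3.86 and -3.66. DNA of other cells with a methylated X chromosome stays open and may contribute: deviations from the stage mean in level and X measure went together over 10 libraries (Pearson r = 0.921, permutation p = 0.00022, adjusted over 8 relations 0.000587; Spearman rho = 0.867, p = 0.00214, adjusted 0.00428; r = 0.915 without the 2 farthest). Neither biological differences between oocytes of a stage nor the different sets of tiles that libraries measured were tested.

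Type6 lay above Type7 in mean level by 2.70 points ± 1.11 (SE), while Type7 minus Type6 was -0.353 over every site a library measures (exact permutation, adjusted p 0.8) and -0.719 with reads pooled over sites (exact permutation, adjusted p 1). The slope on the X measure in the earlier stages predicted 4.35 ± 1.12, so DNA that moves with the X measure may account for the mean. In autosomal tiles that fell it stays open: called without 1 library of each stage, they differed in the pair left out by 11.5 points ± 3.05 (SE, mean of 9 pairs) against 6.15 ± 1.29 predicted, and 1 pair had 14 tiles, too few to decide, though 9 of 9 pairs lay above their prediction and the pair of replicates 3, with an X difference of -0.0913, differed by 6.87 in 127 tiles against -0.144 predicted. With at most 10 reads per site the difference was 2.65. Drawing reads at random leaves the expected level of a site unchanged, so this cannot decide on depth, which stays open. A difference between the 2 stages themselves stays open and was not tested apart.

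CpG-dense tiles lagged in secondary follicles. In tiles matched on start and end level the difference was -6.44 ± 3.49, below 0 in 13 of 13 libraries (exact permutation p = 0.000244, the smallest possible), and with at most 10 reads per site -5.97 (exact permutation p = 0.0022). By stage the matched tiles gave -4.09 in Type3b, -5.64 in Type4, -5.99 in Type5a, -8.51 in Type5b and -8.70 in Type6, below 0 in every library of these stages. In matched tiles without the libraries of X measure above 0 it was -5.41, below 0 in 8 of 8 (exact permutation p = 0.00781, the smallest possible), though in unmatched tiles it missed the threshold. The matched tiles argue against start and end level as the whole cause. Depth is not decided, as drawing reads at random leaves the expected level of a site unchanged. The lag did not rest on libraries of X measure above 0. DNA of other cells is still not excluded: 0 lies above the mean X measure of Type2 (-2.51) and Type7 (-4.98), so libraries kept may hold some. A lag of CpG-dense regions may be biological, as a hypothesis found and tested on the same data.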

How the results depend on the processing

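Of 112 adjacent differences in mean level under alternatives, 104 kept their direction and side of the threshold and 8 reversed. No adjacent difference passed and 3 against 3 libraries cannot go below an exact p of 0.1, so this says nothing about stability: Type7 minus Type6 went from -2.70 to -0.353 over every site a library measures, -0.719 with reads pooled over sites and -1.20 without the libraries of X measure above 0. The last of these left 1 library in Type6. Of 329 values of named tiles, 274 kept direction and side of the threshold, 55 kept the direction but missed the threshold and 0 reversed. These covered other read minimums, at most 10 reads per site and each library left out, where the tile was still tested. Named tiles were picked without overlap of libraries, so leaving out a library cannot reverse them and 0 is no sign of stability. The share of variance between stages was 65.0 to 96.2% under the alternatives other than leaving out a library. With a level of at least 80% in all 3 Type1 libraries in place of 50%, 139 tiles counted as methylated in Type1. A minimum of 1 read equals the files' floor of 3 reads and was run as such. The promoter and gene-list alternatives were not run. Where calls changed, the cause was not tested unless stated; site and library minimums change the tiles tested. On simulated reads the model called 60 and 62% of tiles changed by 30 points, so low counts are no sign of no change. At 20 points it called 18 and 26%, in part because a call itself needs a difference of at least 20 points.

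Tiles called moved by over 1.5 times as follows. With a minimum of 10 reads, Type4 against Type3b gave 2; with 3 reads, Type2 against Type1 gave 7, Type3a against Type2 3 and Type4 against Type3b 12. With at most 10 reads per site the counts were 0 for Type2 against Type1, 0 for Type3a against Type2, 3 for Type3b against Type3a, 5 for Type5a against Type4 and 558 for Type6 against Type5b. With 500-bp tiles they were 1 for Type2 against Type1, 7 for Type4 against Type3b and 11 for Type5a against Type4. With 1 site per tile, where many more tiles were tested, they were 10, 5, 1, 13, 24, 8245, 3059 and 771 for the adjacent pairs in order and 28733 for Type7 against Type1. A fit on the 2 stages gave 0 for Type2 against Type1, 4 for Type3b against Type3a, 0 for Type4 against Type3b, 1725 for Type5b against Type5a, 198 for Type6 against Type5b and 17 for Type7 against Type6.

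With limma the counts were 6 for Type3a against Type2, 6 for Type3b against Type3a, 24 for Type4 against Type3b, 100 for Type5a against Type4 and 648 for Type7 against Type6. With edgeR they were 14 for Type2 against Type1, 2 for Type3b against Type3a, 37 for Type4 against Type3b, 96 for Type5a against Type4 and 1656 for Type5b against Type5a. With the X measure as covariate in limma, chosen after seeing the data and approximate where values are missing, they were 4, 7, 13, 46, 4796 and 660 for the pairs from Type3a against Type2 to Type6 against Type5b.

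Without the 9 libraries of X measure above 0, also chosen after seeing the data, mean differences reversed to 0.605 for Type2 against Type1, -1.28 for Type3a against Type2, -2.27 for Type4 against Type3b and 1.26 for Type5a against Type4. The counts were 20 for Type2 against Type1, 73 for Type3b against Type3a, 61 for Type4 against Type3b and 256 for Type5a against Type4. Of the tiles called with all libraries, 0 of 4 were among them for Type2 against Type1, 0 of 1 for Type3a against Type2 and 1 of 4 for Type4 against Type3b. The counts were 3914 with 2076 of the 2856 for Type5b against Type5a, 1440 with 540 of the 1150 for Type6 against Type5b, 523 with 147 of the 367 for Type7 against Type6, where Type6 kept 1 library, and 7101 with 5769 of the 10164 for Type7 against Type1. The timing difference was -6.00 (exact permutation p = 0.0781).

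The replicate numbers showed little pairing of the libraries: 4 of 23 same-numbered pairs had a correlation over 0.1. Over all pairs of different stages the mean was 0.00608 (highest 0.315) with the same number and -0.00144 (highest 0.354) with different numbers. Weak correlations do not exclude a shared animal or batch. With the replicate block the mean difference of Type3b against Type3a reversed to -1.03, and the counts were 7 for Type2 against Type1, 4 for Type3a against Type2, 3 for Type5a against Type4, 55 for Type5b against Type5a, which share 1 number, and 192 for Type7 against Type6. It moved no other count by over 1.5 times.

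Leaving out each library in turn gave a share of variance between stages of 73.3 to 82.4%. Mean differences ran from -3.63 to 0.605 for Type2 against Type1 (reversed without Type1 replicate 3), -1.28 to 5.94 for Type3a against Type2 (reversed without Type3a replicate 1), -0.0685 to 7.15 for Type3b against Type3a (reversed without Type3a replicate 4), 1.89 to 5.75 for Type4 against Type3b, -4.40 to -0.537 for Type5a against Type4, 4.20 to 6.53 for Type5b against Type5a, 6.94 to 8.79 for Type6 against Type5b and -3.46 to -1.66 for Type7 against Type6. Tile counts ran from 0 (without Type1 replicate 1) to 8 (without Type2 replicate 1) for Type2 against Type1, 0 to 2 for Type3a against Type2, 3 to 13 for Type4 against Type3b, 0 to 19 for Type5a against Type4, 676 to 2709 for Type5b against Type5a, 569 to 1169 for Type6 against Type5b, 121 to 572 for Type7 against Type6 and 5240 to 9243 for Type7 against Type1. The count for Type3b against Type3a stayed at 0. The timing difference ran from -5.73 to -4.01 and the Type1 count from 2655 to 7051 (without Type1 replicate 2).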

Other observations

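The tests in this part on sequence context were chosen after the data were seen. Within 6247 gained tiles, 25521 sites were sorted by the bases beside the CpG into 9 contexts, MspI sites left out. Each site was compared with the mean of the sites of its tile, itself included. Sites flanked by T and A (TCGA, 954 sites) lagged: they lay -6.63 points ± 1.35 (n = 3) from their tile in Type5b, -3.79 ± 1.20 (n = 5) in Type5a and -2.54 ± 0.279 (n = 3) in Type6, but -1.74 ± 1.16 (n = 5) in Type4, near the -1.44 ± 0.214 (n = 3) of Type7. The secondary libraries minus Type7 gave -2.21, below 0 in 11 of 13 (exact permutation p = 0.00269, adjusted over 9 contexts 0.00345), so these sites may gain later. A strain variant carried by every library would lower a site in proportion to its level and is argued against: the deviation in Type5b minus that in Type7 was -5.18 ± 0.788 (SE). No other technical explanation was tested. Flanks of T and A alone do not mark the lag: ACGT sites (1194) gave -0.220, below 0 in 7 of 13 (exact permutation, adjusted p 0.35). ACGA sites gave -1.06 in 13 of 13, CCGA sites -1.18 in 12 of 13 and ACGG sites -0.706 in 12 of 13. Above 0 were GCGC sites (2517) at 0.995, below 0 in 2 of 13, ACGC sites at 0.508, below 0 in 4 of 13, and CCGC (5585) and GCGA sites at 0.970 and 0.702, below 0 in 0 of 13. Deviations within a tile sum to 0, so contexts above 0 in part mirror those below and are not separate results.

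Y chromosome reads were listed in every library, at 74.7 to 239 RPM. Median levels of CpG-dense tiles lay between 0 and 0.390% in every library. Type5a replicate 1 had 26.6% in the tiles low in Type1 and Type2 and high in Type7, with an X measure of -3.86.

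Other splits of the same libraries were run through the tile model. For Type5b against Type5a, 1 of 56 splits, the real one, gave as many as 2856 calls (highest other 797). This argues against chance there but does not exclude it. The share is the smallest that 56 splits allow and is not adjusted over the 9 comparisons. With 10 splits a share under 0.05 is out of reach: the real count and the highest other were 4 and 2 for Type2 against Type1 (1 of 10 as large), 1 and 1 for Type3a against Type2 (3 of 10), 1150 and 186 for Type6 against Type5b (1 of 10), 367 and 166 for Type7 against Type6 (1 of 10), and 10164 and 2348 for Type7 against Type1 (1 of 10). For Type4 against Type3b, 33 of 56 splits gave as many as 4, so chance cannot be excluded. The real count was 0 for Type3b against Type3a (10 of 10 splits as large, highest other 3) and for Type5a against Type4 (100 of 100 drawn from 126), which any split reaches, so the splits decide nothing there. The highest other splits called 1552 tiles for Type4 against Type3b and 5331 for Type5a against Type4, which points to a structure of the samples: the 5331 came from setting Type4 replicates 1, 2 and 5 and Type5a replicates 5 and 7, the libraries of X measure above 0, against the rest.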
